A study of Mus musculus with 16 samples.

How the data were processed

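H3K36ac chromatin immunoprecipitation followed by sequencing was performed on female mouse embryonic stem (ES) cells that were wild type (WT) or lacked SIRT7 (KO). The labels give the strain as a C57BL6/CAST hybrid and the design as mus/cas. Cells were kept in LIF, the cytokine that holds ES cells undifferentiated, through day 0, or sampled 7 days after LIF was withdrawn. The 8 immunoprecipitated samples fall into 4 groups of 2 replicates (KO day 0, KO day 7, WT day 0 and WT day 7). The series also holds 8 input samples, which were not analysed here. Whether the replicates are separate cultures, separate clones or repeats of 1 culture is not stated, so the p-values measure only the spread between these samples, and that spread may be technical. The extraction protocol names antibodies from a pair of suppliers without saying which sample received which, and it names spike-in nucleosomes, but the deposited lists carry no spike-in scaling.

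Per the submitters' processing notes, reads were checked with FastQC 0.11.3, trimmed with Trimmomatic 0.36, aligned to build mm10 with Bowtie2 2.2.9 and handled with SAMtools 0.1.19 and deepTools 2.4.2, and peaks were called with MACS2 2.2.7.1. The tool that assigned reads to alleles, the read filters and the peak threshold are not given in the sources used here. Each sample has 4 deposited peak lists in broad-peak format, from reads assigned to genome1, from reads assigned to genome2, from unassigned reads and from the whole genome. A further 16 lists hold peaks called on the pooled replicates of each group, which makes 48 lists in all. Which strain genome1 and genome2 stand for is not stated, so the names are used as the lists give them. The deposited fold per peak is the authors' ratio of the peak's signal over its background. The deposited significance values per peak are the authors' −log10 p and −log10 q. The deposited score per peak is the authors' score, which was checked to equal the whole-number part of 10 times the −log10 q. The smallest −log10 q was about 1 in each list. Read depth per sample is unknown, because the lists hold no counts, so no counting interval is given, and the number of peaks and the covered length stand in for depth.

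Peak names carry a date, which was 2021 for replicate 1 and 2023 for replicate 2 in each of the 4 groups. Replicate number and date therefore cannot be separated, and equal replicate numbers share a date. Deviations of the genes from their group mean, taken in replicate 2, correlated across genes at 0.118, 0.203, 0.0622, 0.0992, 0.225 and 0.333 in the 6 pairs of groups. Genes are not independent replicates, and no test was made. Replicate number was therefore tried as a block, and values within each date are given beside the main results.

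Covered length differed widely between samples. For the main tests, the peaks of each list were ranked by the authors' −log10 q and kept from the top until the covered length reached that of the shortest of the 8 lists of its kind, which was 13.8 Mb for whole-genome lists, 7.42 Mb for genome1 lists and 2.58 Mb for genome2 lists. These are called lists of equal length. Chromosome coverage was the share of a chromosome's length covered by peaks divided by the share of all autosomal length covered, on the log2 scale with 1 kb added. The allelic skew was the log2 ratio of this value in the genome1 list to that in the genome2 list, so a library-wide difference between alleles cancels. Both were fitted with limma 3.58.1 over the 19 autosomes and X with 4 groups in 1 model, and p-values were adjusted with the Benjamini-Hochberg method over the 20 chromosomes. An exact two-sided permutation test was made for X, with 36 arrangements within day or genotype, which cannot give a p under 0.0556, or 16 arrangements within date, which cannot give a p under 0.125.

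Genes came from a RefSeq table of mm10 with 34337 genes, of which 1256 lie on X. The table has no strand, so the gene interval was the gene with 2 kb on both sides, in place of the planned gene body with 2 kb upstream of its start. The planned promoter window became 1 kb either side of both gene ends. Overlapping and neighbouring genes can share a peak. The fraction of each interval covered was transformed by the arcsine of its square root and fitted with limma with a trend, for genes covered in at least 2 samples (9546 genes, 236 on X). P-values were adjusted over genes with the threshold at 0.05. Effects of genes are differences on this transformed scale. The 6 contrasts fixed before the data were examined were KO minus WT at day 0, at day 7 and averaged over days, day 7 minus day 0 in WT and in KO, and the difference of the day effects. Day 7 minus day 0 averaged over genotypes was added after seeing the data. The tests were checked on simulated data: after a shift of 0.5 was added to 200 of the 9546 genes in 20 simulations, 63.6% of these genes were called between days, 64.0% between genotypes over both days and 43.5% between genotypes at day 7, with 5.2, 4.75 and 3.95 false calls on average. The simulated values were normal and independent between genes and samples. The real values are bounded fractions, many of them 0, so these rates may not hold for them.

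The 19 gene lists were fixed before the data were examined: sirtuins, the X inactivation centre, X genes known to escape inactivation, X inactivation silencing factors, naive pluripotency, general pluripotency, the LIF and STAT3 pathway, formative and primed pluripotency, primitive streak and mesoderm, endoderm, neuroectoderm, trophoblast, fibroblast (feeder) markers, Hox genes, imprinted genes, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, DNA double-strand break repair and housekeeping genes. All X-linked genes were tested as a further set. Each member was found in the gene table, apart from Tbxt, which stands there under its other symbol T. The sets were tested with camera (limma) at a preset correlation of 0.01, adjusted over sets within a contrast, with the estimated correlation as an alternative, and with fry for direction. The genes named were Sirt7 and the X inactivation centre list, per contrast the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold whose direction held in all pairs of samples (the 5 per direction with the smallest p where none passed), and per list up to 4 members with the smallest p. That rule and the main tests were also fixed before the data were examined. Any gene named outside that rule is said to be so.

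Allelic calls counted X genes and autosomal genes with a peak overlapping their interval by 1 base in the genome1 list, the genome2 list or both. Overlap between samples was the Jaccard index of covered bases over the 28 pairs of samples. Pooled lists were compared by the percent of peaks overlapping by 1 base, and by genes with a peak within 1 kb of an end. Windows of 5 Mb were classed by the genome2 share of allele-assigned covered length as low (under 20%) or shared (40% or more, with no upper limit). Alternatives fixed before the data were examined were the replicate block, lists as deposited, peaks ranked by fold, only peaks with a −log10 q of 3 or more, each replicate left out in turn, numbers of peaks in place of covered length, the median autosome as reference, genes covered in any 1 sample, the log2 of covered kb plus 0.5, an estimated correlation, reciprocal overlap of 50%, a 10% minimum of the interval, and wider windows at gene ends. Alternatives chosen after seeing the data were equal numbers of peaks, lists as deposited with the replicate block, equal length within each date with the replicate block (also with chromosomes 6, 8 and 11 left out of the autosomes), gene bodies without flanks and windows at gene ends. The tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Matplotlib 3.10.9, R 4.3.3 and bedtools 2.31.1.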

Results

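The mark measured was acetylation of histone H3 at lysine 36 (H3K36ac) in female hybrid ES cells with and without SIRT7, a nuclear deacetylase of the sirtuin family. The whole-genome lists as deposited held 13218 peaks over 14.0 Mb and 71643 peaks over 122 Mb in WT day 0 (replicates 1 and 2). They held 15479 peaks over 13.8 Mb and 53197 peaks over 81.8 Mb in WT day 7. The KO lists held 39827 peaks over 50.7 Mb and 74843 peaks over 145 Mb at day 0. At day 7 they held 33467 peaks over 38.8 Mb and 76404 peaks over 189 Mb. KO lists were longer than WT lists in all 4 pairs matched for day and date, by 1.20 on the log2 scale of covered length on average (exact two-sided permutation p = 0.333, and 0.125 within date, the smallest value that test allows). The log2 number of peaks differed by 0.82 between genotypes (exact permutation p = 0.333 and 0.125 within date). Between days it differed by −0.11 (exact permutation p = 0.833), and covered length differed by −0.15 between days (exact permutation p = 0.722). Read depth is unknown, so how much of this follows depth cannot be read from the lists.

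In lists of equal length, samples of the same day shared more covered bases than samples of different days. The Jaccard index averaged 0.264 ± 0.0984 (SD, 4 pairs) within groups and 0.286 ± 0.0727 (8 pairs) between genotypes at the same day. It averaged 0.177 ± 0.0612 (8 pairs) between days within a genotype and 0.157 ± 0.0505 (8 pairs) when both differed. Replicates of a group always differ in date. The 4 pairs between genotypes at the same day that also differ in date gave 0.269, 0.208, 0.357 and 0.160, against 0.397, 0.256, 0.160 and 0.241 within groups. Pairs of different groups averaged 0.234 ± 0.0814 (12 pairs) with the same date and 0.179 ± 0.0786 (12 pairs) with different dates. The order by day was weaker in the lists as deposited, with 0.185 within groups, 0.226 between genotypes at the same day, 0.184 between days within a genotype and 0.151 when both differed. Date then separated pairs more, with 0.231 for the same date and 0.143 for different dates. Of the pooled KO peaks, 55.7% at day 0 and 49.2% at day 7 overlapped a pooled WT peak of the same day. Of the pooled WT peaks, 59.6% and 71.2% overlapped a KO peak.

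The first comparison asked how H3K36ac on the X chromosome differed between undifferentiated cells and cells 7 days after LIF withdrawal, the period in which female ES cells undergo X inactivation. On genome1, X had lost most of its peak coverage by day 7. In lists of equal length, the genome1 length covered on X was 1.30% ± 0.0689 of the autosomal length in WT day 0 and 0.121% ± 0.0465 in WT day 7 (mean ± SD, n = 2 each). In KO it was 1.30% ± 0.310 at day 0 and 0.119% ± 0.126 at day 7 (n = 2 each). On genome2 the same value was 6.92% ± 1.31 and 7.55% ± 0.422 in WT and 7.73% ± 0.291 and 7.91% ± 3.20 in KO (n = 2 each). The genome1 values at day 7 rest on few X peaks. These were 12 and 1 (2.2 kb) in KO replicates 1 and 2, and 6 in WT replicate 1. The size of the fall in KO therefore leans on 1 peak and on the 1 kb added. The ratio of genome1 to genome2 coverage of X fell by 3.47 on the log2 scale in WT (SE 0.44, limma adjusted p = 5.42e-05) and by 3.70 in KO (SE 0.44, adjusted p = 2.66e-05). These day effects differed by −0.23 (SE 0.63, adjusted p = 0.988, 95% interval −1.58 to 1.12).

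Genome1 coverage of X alone fell by 3.53 over both genotypes (SE 0.50, limma adjusted p = 0.00601). The value was −3.33 in WT (adjusted p = 0.0550) and −3.73 in KO (adjusted p = 0.0304, and 0.0541 with replicate number as a block). The KO value had an adjusted p of 0.208 without KO day 0 replicate 1, 0.119 without KO day 0 replicate 2. It was 0.0670 without either replicate of WT day 0 and 0.0735 without either replicate of WT day 7. With 1 replicate left out, the WT value ran from −3.69 to −2.97. Each fit with 1 replicate left out loses the spread of 1 group, so the p-values of such fits are rough, here and below. For X coverage, those without a replicate of KO day 7, whose replicates lay furthest apart, are not given. Within date and without the added 1 kb, the day difference of genome1 coverage was −3.94 in replicate 1 and −3.02 in replicate 2 of WT. In KO it was −2.87 and −5.18. Genome2 coverage differed by 0.05 (SE 0.20, adjusted p = 0.916). In whole-genome lists, X covered 3.77% ± 0.0620 of the autosomal length in WT day 0 and 2.10% ± 0.181 in WT day 7. It covered 4.13% ± 0.140 and 2.17% ± 1.11 in KO (n = 2 each). Day 7 was below day 0 in all 4 pairs matched for genotype and date, with log2 values of −0.95 and −0.74 in WT and −0.52 and −1.55 in KO. The averaged difference of −0.94 (SE 0.21) had an adjusted p of 0.0501 from limma and an exact permutation p of 0.0556, the smallest possible. The adjusted p was 0.0294 with replicate number as a block. In WT alone it was −0.85 (SE 0.30, adjusted p = 0.465) and in KO alone −1.03 (SE 0.30, adjusted p = 0.188). Without KO day 7 replicate 2, the sample with the lowest X coverage, the KO value was −0.48 and the averaged value −0.66. Without KO day 7 replicate 1 they were −1.58 and −1.21. The gap between these replicates then no longer enters the spread, so no p-value is given for these fits.

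**Figure D1:**
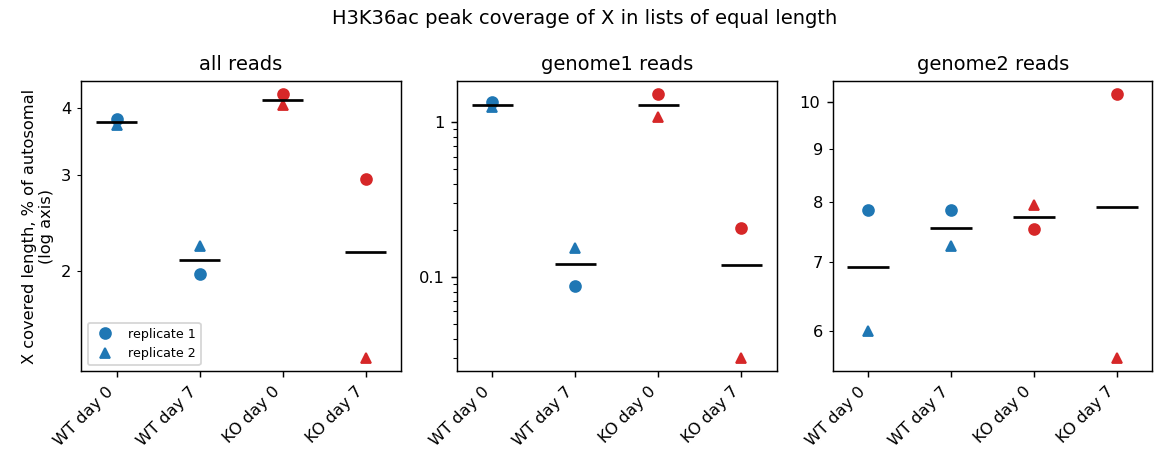
Length covered by H3K36ac peaks on X as a percent of the autosomal covered length (log axis), per replicate and as group means (lines, n = 2), in lists of equal length from all reads, genome1 reads and genome2 reads. Genome1 group means are 1.30% at day 0 in both genotypes and 0.121% (WT) and 0.119% (KO) at day 7, while KO day 7 is the group whose replicates lie furthest apart on the log axis in each panel.

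Single genes on X showed the same shift between alleles. In lists of equal length, genes with a peak on genome2 only made up 53.0% and 39.0% of the X genes with an allele-assigned peak in WT day 0 (replicates 1 and 2). They made up 97.5% and 93.3% in WT day 7. In KO they made up 37.2% and 54.3% at day 0, and 93.0% and 100% at day 7. These shares rest on 26 to 159 X genes per sample, the fewest in KO day 7 replicate 2. The share of X genes with a peak on 1 allele only was 39.7 points higher at day 7 (exact permutation p = 0.0556, the smallest possible, and 0.125 within date, also the smallest). For autosomal genes it differed by −0.80 points (exact permutation p = 0.556). The autosomal share was already 80.8% to 90.5% per sample, against 50.0% to 64.9% on X at day 0, so it had less room to rise. Between genotypes the share of X genes differed by −1.66 points (exact permutation p = 0.667). In the lists as deposited it differed by −13.9 points (exact permutation p = 0.167, and 0.125 within date, the smallest possible).

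In the lists as deposited, 29 and 186 X genes had a genome1 peak in KO day 7 and 4 and 104 in WT day 7 (replicates 1 and 2). Ddx3x (chromosome X, 13280496 to 13293988), an RNA helicase gene known to escape X inactivation, its neighbour Gm34661 (13343546 to 13347704) and the noncoding gene Kis2 (52742563 to 52744593) had a genome1 peak in each of the 4 day 7 samples. At Ddx3x, genome1 peaks covered 17.5% and 28.8% of the gene with its flanks in KO day 0 and 17.6% and 27.98% in KO day 7 (replicates 1 and 2). They covered 5.28% and 27.1% in WT day 0 and 6.39% and 15.3% in WT day 7. The 22 genes with one in 3 of the 4 include the histone demethylase gene Kdm6a, Firre, Xist, Tsix, Ftx, Bcor, Ogt, Porcn, Ebp and Zrsr2. In the pooled lists, genome1 peaks were kept at 9 of 10 genes of the escape list with a day 0 peak in KO, against 175 of 507 other X genes (34.5%, Fisher's exact p = 0.000556). In WT they were kept at 9 of 11, against 95 of 383 (24.8%, Fisher's exact p = 0.000159). Within date, KO gave 3 of 7 against 24 of 271 (Fisher's exact p = 0.0221) and 9 of 10 against 171 of 516 (p = 0.000395, Fisher's exact). WT gave 1 of 4 against 3 of 100 (p = 0.147, Fisher's exact) and 9 of 11 against 94 of 386 (p = 0.000137, Fisher's exact). These tests treat genes as independent, although neighbours can share a peak. In the pooled lists, escape genes also had stronger day 0 genome1 peaks (median −log10 q of 21.95 against 9.36 in KO and 20.9 against 8.63 in WT). Other X genes of like strength kept on average 5.63 of 10 in KO and 5.21 of 11 in WT. Genes outside the fixed lists in this paragraph were named after their values were seen.

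At the X inactivation centre, Tsix (X, 103431517 to 103484957), the antisense repressor of Xist, was covered over 15.1% ± 4.01 in WT day 0 and 4.41% ± 4.49 in WT day 7. In KO the values were 15.5% ± 0.793 and 2.00% ± 2.83 (n = 2 each, lists of equal length). In the lists as deposited they were 32.0% ± 10.8 and 15.8% ± 9.09 in KO and 23.9% ± 16.5 and 6.82% ± 7.90 in WT, so at day 7 the order of KO and WT turned. Rlim (X, 103957163 to 103981296), a ubiquitin ligase gene that activates Xist, was covered over 10.7% ± 2.18 and 8.84% ± 4.15 in WT and 12.3% ± 0.540 and 5.57% ± 7.88 in KO. The last value includes a 0 in replicate 2 that came from the cut to equal length, and it was 12.0% ± 1.20 in the lists as deposited, above WT. Xist (X, 103460373 to 103483233), the RNA that coats the inactive X, lies inside Tsix, so the same peaks count for both. It was covered over 4.48% ± 4.24 and 4.22% ± 4.42 in WT and listed at 0 in KO. In the lists as deposited KO had 9.97% ± 11.6 and 12.5% ± 10.0, against 6.96% ± 7.73 and 5.11% ± 5.69 in WT. Ftx was covered over 0.302% ± 0.427 and 2.26% ± 0.0889 in WT and listed at 0 in KO, where the lists as deposited had 5.51% ± 4.11 and 10.7% ± 6.54, against 4.42% ± 5.40 and 5.10% ± 4.11 in WT. Jpx and Chic1 had such a peak in WT at most, and Cdx4, Tsx, Zcchc13 and Nap1l2 had none in lists of equal length. The 4 testable genes of this list did not pass for any contrast, with a camera adjusted p of 0.394 between days and 0.127 between genotypes. Adjusted over the list alone, 2 genes (Xist and Ftx) were lower in KO over both days. In the lists as deposited the means of both were higher in KO, so the direction rests on the cut to equal length.

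The second comparison asked which genes gained or lost H3K36ac between day 0 and day 7. Averaged over the genotypes, a contrast added after seeing the data, 118 genes rose and 58 fell (limma, 9546 genes). Of these 176, 170 moved the same way in all 8 pairs of samples, which a call in the same samples makes likely. Fgf8 (chromosome 19, 45736491 to 45742941), a growth factor of the primitive streak, was listed at 0 at day 0 and covered over 83.7% ± 23.1 in KO day 7 and 50.5% ± 18.8 in WT day 7 (effect 1.03, adjusted p = 0.0326). Sp5 (chromosome 2, 70474923 to 70477726), a WNT target transcription factor, went from 0 to 73.8% ± 9.88 in KO and 58.0% ± 13.0 in WT (effect 0.95, adjusted p = 0.0287). Irx3 (chromosome 8, 91798511 to 91801654), a homeobox gene, went from 0 to 75.8% ± 21.5 and 62.8% ± 40.6 (adjusted p = 0.0410).

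The stress response genes Gadd45b (chromosome 10, 80930091 to 80932204) and Gadd45g (chromosome 13, 51846675 to 51848475) were covered over 91.4% ± 12.2 and 88.3% ± 16.6 in KO day 7 and 71.3% ± 33.7 and 75.4% ± 22.2 in WT day 7. At day 0 coverage was 0 for Gadd45b and up to 4.51% ± 6.38 for Gadd45g (adjusted p = 0.0316 and 0.0331). The other genes with the largest gains were Gm40288, Gm11772, Gm14488, Ier5l and 1700020G03Rik (adjusted p of 0.0287 to 0.0457). Among the losses, Ooep (chromosome 9, 78376903 to 78378588), an oocyte and early embryo gene, was covered over 82.3% ± 17.9 in KO day 0 and 64.5% ± 5.87 in WT day 0 and listed at 0 at day 7 (effect −1.05, adjusted p = 0.0287). H2-M5 (chromosome 17, 36983785 to 36997955), a nonclassical MHC class I gene, went from 92.5% ± 10.6 to 0 in KO and from 58.2% ± 4.83 to 2.05% ± 2.90 in WT (adjusted p = 0.0287). Rbmxl2, Ly6g6e and the noncoding or uncharacterised genes Gm13056, 1700097N02Rik, Gm11496, Gm30875, Gm34250 and Gm35891 completed the losses (adjusted p of 0.0287 to 0.0465).

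**Figure D2:**
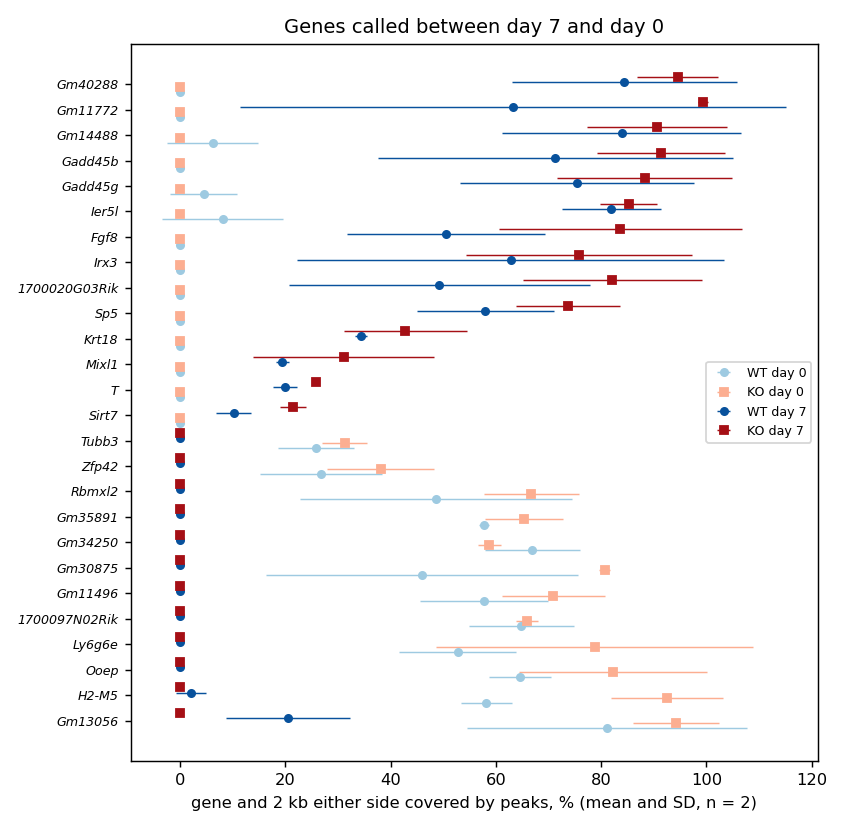
Percent of each gene with its 2 kb flanks covered by H3K36ac peaks (mean and SD, n = 2) in the 4 groups, for the genes with the largest changes between days and the members of the fixed lists past the threshold. Sp5 lies at 0 at day 0 and at 73.8% (KO) and 58.0% (WT) at day 7, and Ooep goes from 82.3% and 64.5% to 0.

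Naive pluripotency genes fell as a set (camera adjusted p = 2.33e-06 over 13 genes, adjusted p = 0.108 with an estimated correlation). Of these, 1 passed over all genes and 5 (Zfp42, Dppa5a, Nr0b1, Tcl1 and Esrrb) fell when adjusted over the list alone. Zfp42 (chromosome 8, 43295067 to 43307009), the Rex1 gene of undifferentiated cells, was the gene that passed, going from 38.1% ± 10.2 to 0 in KO and from 26.8% ± 11.6 to 0 in WT (adjusted p = 0.0301). Dppa5a went from 75.3% ± 35.0 and 76.4% ± 33.4 to 0 (adjusted p = 0.0549), and Nr0b1 from 50.0% and 19.9% to 0 (adjusted p = 0.0546), neither past the threshold over all genes. The general pluripotency set also fell (camera adjusted p = 0.0181 over 12 genes, adjusted p = 0.546 with an estimated correlation), with 0 genes called by limma over all genes or adjusted over the list alone. Its adjusted p was 0.242 without KO day 0 replicate 2, 0.136 without WT day 0 replicate 2 and 0.0627 without WT day 7 replicate 1. Its member Pou5f1, the Oct4 gene, was covered over 58.2% at day 0 and 18.7% at day 7 in KO and over 45.1% and 13.9% in WT (adjusted p = 0.222).

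Primitive streak and mesoderm genes rose as a set (camera adjusted p = 6.94e-05 over 9 genes, adjusted p = 0.424 with an estimated correlation), with 2 past the threshold over all genes and 7 adjusted over the list alone. T (chromosome 17, 8434423 to 8442496), the brachyury gene, went from 0 to 25.8% ± 0.474 in KO and 20.0% ± 2.27 in WT (adjusted p = 0.0287). Mixl1 (chromosome 1, 180693043 to 180697034) went from 0 to 31.1% ± 17.2 and 19.5% ± 1.29 (adjusted p = 0.0343). Trophoblast genes rose (camera adjusted p = 0.0181 over 6 genes, adjusted p = 0.424 with an estimated correlation), with 1 over all genes and 3 (Krt18, Hand1 and Cdx2) adjusted over the list alone. The set's adjusted p was 0.0627 without KO day 7 replicate 2, 0.343 without WT day 0 replicate 2 and 0.146 without WT day 7 replicate 1. The gene past the threshold was the keratin gene Krt18 (chromosome 15, 102028216 to 102032026), which went from 0 to 42.8% ± 11.7 and 34.3% ± 1.19 (adjusted p = 0.0287). The neuroectoderm list gave a camera adjusted p of 0.744 over 6 genes. Its member Tubb3 (chromosome 8, 123411553 to 123422015), a neuronal tubulin gene, fell from 31.3% ± 4.30 and 25.9% ± 7.22 to 0 (adjusted p = 0.0287). Sirt7 itself (chromosome 11, 120618371 to 120625014) was listed at 0 at day 0 and covered over 21.5% ± 2.48 in KO day 7 and 10.2% ± 3.30 in WT day 7 (adjusted p = 0.0316). In the lists as deposited it was covered over 24.6% ± 14.5 and 33.4% ± 19.4 in KO (day 0 and day 7) and over 18.6% ± 26.3 and 14.4% ± 9.29 in WT, where the direction turned. A peak over the gene says nothing about where the deletion lies.

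X-linked genes fell as a set relative to autosomal genes (camera adjusted p = 1.99e-08 over 236 genes, adjusted p = 0.424 with an estimated correlation), with 3 past the threshold over all genes and 1 adjusted over the set alone. The 3 genes, named after their values were seen, were Eras, a Ras gene of undifferentiated ES cells, Elk1 and C430049B03Rik. Cytosolic ribosomal protein genes fell (camera adjusted p = 0.0181 over 35 genes, adjusted p = 0.819 with an estimated correlation), with 0 genes called by limma. This call was absent without KO day 0 replicate 2 (adjusted p = 0.106), KO day 7 replicate 1 (0.0638), WT day 0 replicate 2 (0.972) or WT day 7 replicate 1 (0.160). The remaining lists did not pass between days, with camera adjusted p of 0.140 (LIF and STAT3 pathway), 0.180 (imprinted genes), 0.254 (endoderm), 0.381 (sirtuins and Hox genes). They also gave 0.471 (formative and primed pluripotency, and mitochondrial ribosomal proteins), 0.744 (escape genes and housekeeping genes), 0.947 (silencing factors and fibroblast markers) and 0.959 (double-strand break repair). The median of the members was positive where camera gave a lower direction for the neuroectoderm (0.21), fibroblast (0.08), silencing factor (0.02), housekeeping (0.03), double-strand break repair (0.03) and mitochondrial ribosomal (0.01) lists. Adjusted over the list alone, limma also called 3 higher (Fst, Lef1 and Fgf5) and 2 lower (Etv4 and Dnmt3l) formative genes, 2 higher sirtuins (Sirt7 and Sirt3), the imprinted gene Meg3 as higher and Mrps24 as lower. Only 3 fibroblast markers were testable (Vim, Fn1 and Lum), so feeder cells were measured only weakly.

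Within single genotypes, limma called 0 genes between days. At an unadjusted p under 0.05, 930 genes were higher and 301 lower in WT, and 840 higher and 508 lower in KO. The excess of gains in WT depended on the scaling, with 66 higher and 63 lower in lists as deposited, 571 and 973 in these with replicate number as a block, and 471 and 396 with equal numbers of peaks. KO then had 435 and 306, 1931 and 1275, and 1357 and 928. In KO the excess turned to 409 higher and 596 lower without KO day 0 replicate 2, and was 504 and 476 without KO day 0 replicate 1. The smallest adjusted p was 0.0896 in WT, where Gm31951, Rubie, Ccdc97, Gm34263 and B130016D09Rik were higher and Gm34250, Gm46159, 1700097N02Rik, Gm40093 and Gm35891 lower. It was 0.0891 in KO, where Sp5, LOC115486424, Bc1, Tmem59l and Krt18 were higher and C430049B03Rik, Gm35891, 1700097N02Rik, Gm11496 and Mir124a-1hg lower. None of these passed. With a single WT sample left in a group, genes were called between days in WT, but most of them had no spread left within the groups. These calls are therefore not read as day effects. The 176 genes called over both genotypes became 0 without KO day 0 replicate 1, KO day 0 replicate 2 or KO day 7 replicate 2, and also with lists as deposited. The excess of gains turned without WT day 0 replicate 1 (95 rose and 184 fell) and without WT day 0 replicate 2 (49 rose and 137 fell). The counts were 630 and 121 without WT day 7 replicate 1, 489 and 72 without WT day 7 replicate 2, and 215 and 30 without KO day 7 replicate 1.

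The third comparison asked how loss of SIRT7 altered H3K36ac on X. In lists of equal length the genotypes lay within the spread of their replicates at day 7. At day 0 both KO samples (4.23% and 4.04%) lay above both WT samples (3.81% and 3.72%), a difference that did not pass (adjusted p = 0.949). X covered 4.13% ± 0.140 of the autosomal length in KO day 0 against 3.77% ± 0.0620 in WT day 0. It covered 2.17% ± 1.11 in KO day 7 against 2.10% ± 0.181 in WT day 7 (n = 2 each). The difference averaged over days was 0.04 on the log2 scale (SE 0.21, limma adjusted p = 0.933, 95% interval −0.45 to 0.53), with 0.13 at day 0 and −0.05 at day 7. Within date it was 0.15 and 0.12 at day 0, and 0.59 in replicate 1 against −0.69 in replicate 2 at day 7. The log2 ratio of genome1 to genome2 coverage of X differed by −0.30 between genotypes (SE 0.31, adjusted p = 0.882, 95% interval −0.98 to 0.37) and genome1 coverage by −0.21 (adjusted p = 0.975).

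This comparison depended on KO day 7 and on how lists were equalised. Without KO day 7 replicate 1 the difference at day 7 was −0.60, and without KO day 7 replicate 2 it was 0.50. Without KO day 7 replicate 1 the day effect in KO minus that in WT was −0.73, against −0.19 with all samples (limma adjusted p = 0.838). Without replicate 2 the difference over both days was 0.32. Fits with 1 KO day 7 sample lose the spread of that group, so their p-values are not given. With equal length within each date and replicate number as a block, an alternative chosen after seeing the data, X was higher in KO by 0.42 (SE 0.06, adjusted p = 1.80e-05), with 0.29 at day 0 and 0.55 at day 7. With chromosomes 6, 8 and 11 left out it was higher by 0.33 (adjusted p = 0.0183). In the same setting the skew differed by 0.55 (SE 0.16, adjusted p = 0.0443) and genome1 coverage by 0.71 (adjusted p = 0.0862), both less skewed in KO. Lists as deposited gave 0.42 for X (adjusted p = 0.0928, and 0.0122 with replicate number as a block) and 0.79 for the skew (adjusted p = 0.135).

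The fourth comparison asked which genes differed between KO and WT, and limma called 0 of 9546 genes at day 0, at day 7, over both days or in the difference of the day effects. At an unadjusted p under 0.05, 227 genes were higher and 321 lower in KO at day 0, and 39 higher and 525 lower at day 7. The counts were 119 higher and 715 lower over both days, and 136 higher and 394 lower in the difference. At day 0 the excess of lower genes turned without KO day 0 replicate 1 (244 higher and 167 lower) or replicate 2 (202 and 120). The direction of these counts also depended on the scaling of the lists. Equal length removes any change in total coverage, so a rise along the whole genome in KO could not show in it. Lists as deposited called 0 genes in each of these contrasts too. At an unadjusted p under 0.05 they gave 227 higher and 7 lower at day 0, 375 and 6 at day 7 and 551 and 13 over both days. With replicate number as a block they gave 2572 and 12, 4278 and 24, and 6878 and 31. Equal numbers of peaks gave 651 and 78, 452 and 55, and 854 and 75. Peaks of a −log10 q of 3 or more gave 178 and 1, 266 and 0, and 464 and 0. The excess of lower genes stayed with peaks ranked by fold (237 and 308, 66 and 500, and 156 and 721) and, less strongly, with equal length within each date (176 and 214, 326 and 514, and 463 and 590). Of the list members tabled over both days (at most 4 per list), 40 of the 42 lower in KO and 0 of the 30 higher in KO turned direction in the lists as deposited. Lists of equal length held fewer and longer peaks in KO, with 0.373 and 0.379 times the WT number in replicate 1 (day 0 and day 7) and 0.535 and 0.471 times in replicate 2. With 1 sample left out, genes were called only where a WT group was down to a single sample. In each of these fits most of the called genes had no spread left within the groups. These calls are therefore not read as differences between genotypes.

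Otx2 (chromosome 14, 48656781 to 48667644), a transcription factor gene of the primed state and the anterior epiblast, was covered over 75.4% ± 34.8 in KO day 0 against 21.1% ± 16.4 in WT. At day 7 it was covered over 100% ± 0 in KO against 16.6% ± 9.11 in WT (n = 2 each, adjusted p = 0.439 over both days and 0.280 at day 7, higher in KO in 8 of 8 pairs). Pim3, a kinase gene downstream of LIF, was covered over 98.8% ± 1.71 and 81.5% ± 13.2 in KO against 12.8% ± 18.1 and 40.4% ± 38.1 in WT (adjusted p = 0.439, 8 of 8 pairs). Lhx1, a gene of mesoderm and endoderm precursors, was listed at 0 in KO and in WT day 0 and covered over 31.2% ± 14.0 in WT day 7 (adjusted p = 0.122 at day 7). Rpl13a, a ribosomal protein gene, was covered over 0 and 7.32% ± 10.3 in KO against 60.6% and 33.0% in WT (adjusted p = 0.453). Ddx3x was covered over 29.5% and 29.1% in KO against 16.1% and 13.4% in WT (adjusted p = 0.669, higher in KO in 8 of 8 pairs). None of these passed. Lhx1 and Rpl13a were higher in KO in the lists as deposited, with effects over both days of 0.27 in each.

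At day 0 the genes with the smallest p, none passing (adjusted p = 0.420), were C430049B03Rik, Mc5r, Inhbc, Gm34110 and N4bp3, higher in KO, and Gm40093, Nfu1, Mrps24, Rnpepl1 and Pycr1, lower in KO. C430049B03Rik (chromosome X, 53053112 to 53057190) was covered over 35.3% ± 6.64 in KO day 0 and listed at 0 in the other groups. At day 7 they were St8sia2, Gm52354, A830052D11Rik, Uqcr11 and Otx2, higher in KO, and Gm31951, Rubie, Ccdc97, Gm34263 and B130016D09Rik, lower in KO (adjusted p of 0.122 to 0.280). Over both days Zfp688 was covered over 12.9% and 14.6% in KO and listed at 0 in WT. Myadm was listed at 0 in KO and covered over 29.5% ± 19.2 and 28.1% ± 2.50 in WT (adjusted p = 0.439 for both). Myadm was higher in KO in the lists as deposited (effect 0.13), where the direction of the genes lower in KO also turned for 2 of 5 at day 0 (Nfu1 and Mrps24) and 3 of 5 at day 7 (Gm31951, Gm34263 and B130016D09Rik). The smallest adjusted p for the difference of the day effects was 0.574.

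As sets over both days, the general pluripotency genes (camera adjusted p = 0.0119 over 12 genes), the naive pluripotency genes (adjusted p = 0.0142 over 13) and the formative and primed genes (adjusted p = 0.0142 over 13) were higher in KO, each with an adjusted p of 0.569 with an estimated correlation. No member passed over all genes, and adjusted over the list alone 1 formative gene (Otx2) and 0 genes of the other two did. At day 0 the naive and general sets were higher (adjusted p = 0.000945 for both, and 0.308 and 0.660 with an estimated correlation) and the cytosolic ribosomal set lower (adjusted p = 0.000422, and 0.888 with an estimated correlation), with 0 genes called by limma over all genes. Adjusted over the list alone, the naive gene Tcl1 and the LIF pathway gene Pim3 were higher and Mrps24 lower. At day 7 no list passed, and Lhx1 was lower adjusted over its list alone, as it was over both days. The remaining lists gave camera adjusted p of 0.0694 (cytosolic ribosomal) to 0.943 over both days. Among them were 0.273 for the LIF and STAT3 pathway and for imprinted genes, 0.276 for silencing factors and 0.846 for sirtuins and escape genes. Without KO day 7 replicate 1 or WT day 7 replicate 2 none of the 3 sets over both days passed (adjusted p of 0.0594 to 0.396). Without KO day 0 replicate 2 the formative set alone did (adjusted p = 0.0466). The naive set also missed the threshold without KO day 7 replicate 2 (0.0641) or WT day 0 replicate 1 (0.0502), and the formative set without WT day 0 replicate 2 (0.257), as adjusted p. For sirtuins, escape genes, neuroectoderm, mitochondrial ribosomal, repair and all X-linked genes, the median or the mean of the members had the opposite sign to the camera direction.

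The genotypes also differed by chromosome. With equal length within each date and replicate number as a block, a setting chosen after seeing the data, the share of coverage on chromosome 6 differed by −0.47 on the log2 scale (KO minus WT, SE 0.07, limma adjusted p = 4.56e-05), that on chromosome 8 by −0.35 (SE 0.07, adjusted p = 0.000337) and that on chromosome 11 by −0.15 (adjusted p = 0.0404). Chromosomes 3, 10, 13 and 14 were higher in KO by 0.25, 0.23, 0.20 and 0.17 (adjusted p = 0.00150, 0.00304, 0.00517 and 0.0299). In this setting 30 of 30 windows of 5 Mb on chromosome 6, 23 of 26 on chromosome 8 and 23 of 25 on chromosome 11 were higher in WT relative to the median autosomal window. For this reason the X values above are given with and without these chromosomes.

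**Figure D3:**
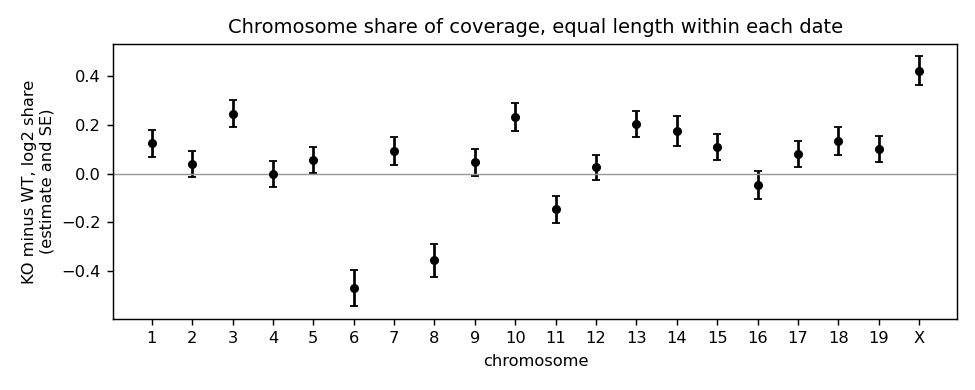
Difference between KO and WT in the share of covered length per chromosome (log2, estimate and SE from limma, both days, 8 samples), in lists of equal length within each date with replicate number as a block. Chromosomes 6 (−0.47) and 8 (−0.35) lie lowest and X (0.42) highest.

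The share of peaks near gene ends was higher at day 7 in each of the 4 pairs matched for genotype and date. Within 1 kb of a gene end lay 53.8% and 67.8% of peaks in KO day 0 and 65.6% and 87.2% in KO day 7. The shares were 27.4% and 72.9% in WT day 0, and 36.9% and 80.9% in WT day 7 (replicates 1 and 2, lists of equal length). The genotypes differed by 14.1 points (exact permutation p = 0.389) and the days by 12.2 points (exact permutation p = 0.444, and 0.125 within date, the smallest possible). Longer peaks reach a gene end more easily. The median width in these lists was 1973 to 4131 bp in KO and 648 to 2130 bp in WT. A difference in width therefore cannot be separated here from one in where the mark lies. In lists as deposited the day difference was 5.99 points (exact permutation p = 0.111, and 0.125 within date) and the genotype difference −0.80 points (exact permutation p = 0.722). In the pooled lists as deposited, 4185 genes had such a peak in KO day 7 and not in WT day 7, and 950 the reverse, with 601 and 15 also so in both replicates. On X these counts were 141 and 9, with 20 and 0 in both replicates, and the KO lists were the longer ones. At day 0, 2430 genes were so in KO and 1864 in WT, with 302 and 12 in both replicates.

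The 2 alleles did not contribute evenly along the autosomes. Over 502 autosomal windows of 5 Mb, the genome2 share of allele-assigned covered length had a median of 12.5%, with 299 windows under 20%, 166 at 40% or more and 37 between. X had a median of 81.5% over both days together. Over the whole of X the share ran from 57.5% to 96.6% between samples, and genome1 coverage of X was low at day 7. Stretches of windows at 40% or more covered chromosome 13 from 0 to 125 Mb, chromosome 5 from 35 to 145 Mb, chromosome 7 from 15 to 130 Mb, chromosome 9 from 20 to 120 Mb, chromosome 8 from 0 to 85 Mb and chromosome 2 from 0 to 70 Mb. Many of these leaned to genome2, with a lowest window of 54.9% on chromosome 13, 57.8% on chromosome 7, 59.3% on chromosome 8 and 59.1% on chromosome 9. Per chromosome the share ran from 3.96% on chromosome 10 to 63.9% on chromosome 13. Shorter such stretches lay on chromosome 6 from 0 to 30 Mb, chromosome 11 from 90 to 125 Mb and chromosome 14 from 0 to 20 Mb. In the 299 windows under 20%, genome2 made up little of the allele-assigned coverage.

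**Figure D4:**
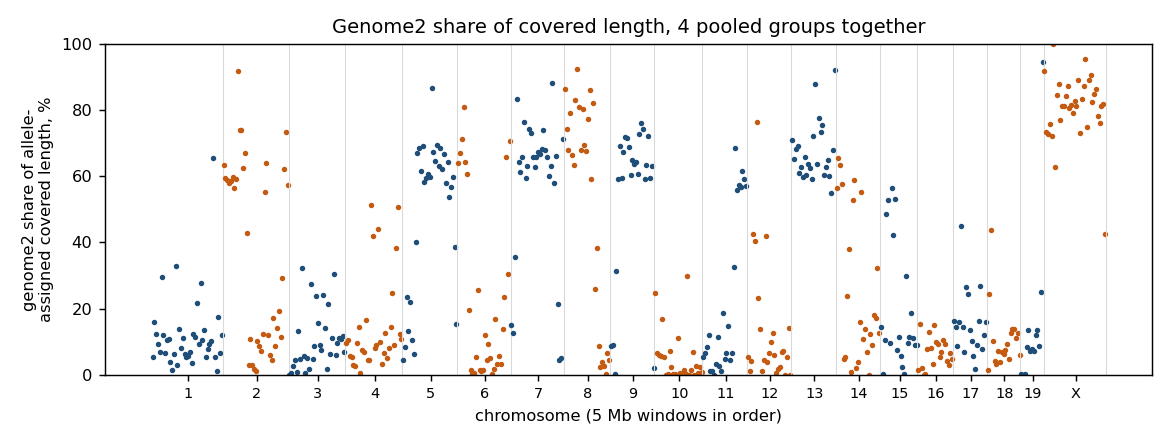
Genome2 share (percent) of the covered length assigned to either allele in consecutive 5 Mb windows along the chromosomes, summed over the 4 pooled groups, with each point 1 window. Chromosome 10 lies near the bottom (3.96%) and chromosome 13 (63.9%) and X (median 81.5%) near the top.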

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

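The tests of a mapping preference, of adjacent windows, of list length and of matched draws, the comparisons of splits and the settings that equalise lists within each date were chosen only after the result was seen, while the tests of variant density and of windows on chromosomes 6 and 8 were set down before their results were seen.

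Cytosolic ribosomal protein genes differed in their day effect between KO and WT, the one list to do so (camera adjusted p = 0.00468 over 35 genes, with a median member effect of 0.16 and 0 genes called by limma). Adjusted p = 0.962 with an estimated correlation. Without WT day 0 replicate 2 the direction turned (adjusted p = 0.814), and the adjusted p was 0.335 without WT day 7 replicate 1, 0.231 without KO day 7 replicate 2 and 0.0502 without KO day 0 replicate 1. The whole-genome lists held 10 to 25 peaks on chromosome Y although the labels give the cells as female, a signal outside the comparisons made here, for which no explanation was tested.

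The first pattern is the low genome1 coverage of X at day 7 in both genotypes. Shorter genome1 lists at day 7 are argued against as the whole cause. Covered length outside X at day 7 over day 0 was 0.669 and 1.52 in KO (replicates 1 and 2) and 0.791 and 0.943 in WT, so 3 of the 4 pairs did shorten. On X the ratio was 0.125 and 0.245 in KO and 0.0510 and 0.185 in WT, and the ratio outside X was at least 5.11 times that on X in each pair. Loss of the genome1 X from all cells is argued against by escape genes, which kept genome1 peaks more often than other X genes of like day 0 peak strength (5.63 of 10 in an average KO draw against 9, with a share of 0.0118 of draws as high, and 0.0076 in WT). Loss from some of the cells stays open, as the lists average over cells. Cells that had not left the undifferentiated state would keep genome1 coverage rather than lower it, so they bear only on the remaining peaks. The pattern is consistent with X inactivation that falls on the genome1 X during differentiation, as a hypothesis found and tested on the same data, and the genotype made no difference past the threshold in lists of equal length. With equal length within each date and replicate number as a block, X coverage was higher in KO by 0.42 (adjusted p = 1.80e-05) and the skew differed by 0.55 (adjusted p = 0.0443), so a genotype effect stays open.

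The second pattern is that chromosomes 6 and 8 took a larger share of coverage in WT than in KO. Unequal list lengths are argued against as the whole cause by the value for chromosome 6 of −0.47 (SE 0.07) after lists had been brought to equal length within each date. Extra copies of chromosomes 6 and 8 in the WT cells stay open, and 94.6% of their windows were higher in WT. These chromosomes were picked for their larger share in the same lists, so a high percent was likely beforehand. Any change along a whole chromosome would give it too, so it cannot decide. On the other autosomes the percent ran from 24 on chromosome 13 to 92 on chromosome 11. Chromosome 11 went the same way in 23 of 25 windows. Copy number itself was not measured, because the inputs were not analysed here, and an effect of SIRT7 on these chromosomes also stays open.

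The third pattern is the autosomal stretches with almost all allele-assigned coverage on genome1. Few variants between the strains in those stretches predicted a lower genome1 length over whole-genome length in them. It was 3.05 times as high as in stretches with a genome2 share of 40% or more (95% interval 2.78 to 3.26, classed on KO and measured in WT). Classed on WT and measured in KO it was 2.13 times as high (2.02 to 2.29). Classing by a low genome2 share favours a high genome1 length beforehand, also across genotypes that share the pattern, so this ratio cannot decide. Unassigned length over whole-genome length, not part of the prediction, was 1.09 times as high (0.934 to 1.21) and 0.979 times as high (0.926 to 1.07). Both intervals include 1, so more unassigned coverage in those stretches was not seen. A uniform mapping preference is argued against by a genome2 share that differed 16.1 times between chromosomes 10 and 13. Low windows lay side by side in 245 pairs against a median of 212 in 10000 shuffles (share 0.0001, the smallest they can give), which restates that the pattern comes in stretches. Segments homozygous for genome1 and a mapping preference that differs between regions cannot be told apart here, because both would put low windows side by side. No biological explanation was tested, since the stretches were found in both WT and KO.

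Other splits of the 8 samples into groups of 4 were compared with the real ones in a model with 2 groups. The split by genotype gave 0 genes past the threshold, a count that all 35 splits reach by construction, so it leaves nothing to compare with chance. The highest of the others, with 356 genes, was the split by day, the main structure of the samples. The split by day itself was the 1 of 35 that gave as many as 356, and the highest other, with 9 genes, was the split by date. The splits did not keep the dates balanced, and the day contrast was added after seeing the data. Chance is therefore not excluded for the day split. In lists as deposited 0 genes were called between days. With replicate number as a block, 92 genes rose and 45 fell between days.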

How the results depend on the processing

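Tests with equal numbers of peaks, with lists as deposited and the replicate block together, with equal length within each date, with windows at gene ends and with gene bodies were chosen only after the result was seen, as was the day contrast over both genotypes; the others were planned. The fall of the genome1 to genome2 ratio of X between days kept its direction under each alternative and each left-out replicate, and lost its call in KO alone under the stricter threshold. The number of replicates and the unknown depth limit the rest: with 2 samples per group the exact permutation tests cannot pass, and KO and WT lists differ in length. The planned promoter window of 1 kb around a start was not run as written, for want of strands. Of the values that answer a comparison, 475 kept their direction and their call or stayed near their count under an alternative or without a replicate, 61 reversed, 36 gained and 11 lost a call, and 78 counts or shares moved. Of 494 values of the 26 named genes called between days over both genotypes, 235 stayed past the threshold, 259 did not and 0 reversed. Most of these genes were named because they passed with the same direction in all pairs of samples. Leaving out a sample could not reverse those, so the 0 is in part fixed by the choice. Other named genes were not followed in this way, and Xist and Ftx, lower in KO in lists of equal length, were higher in KO in lists as deposited. The cause was not tested for any change below unless one is named. Values are log2 differences, numbers of genes, numbers of sets or percents.

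Lists as deposited gave X coverage, KO minus WT, of 0.49 at day 7 and a difference of day effects of 0.14. They gave an allelic skew, KO minus WT, of 0.64 at day 0, 0.94 at day 7 and 0.79 over both days, with 0.30 for the difference of day effects, and genome1 X coverage in WT of −3.05 between days (adjusted p = 0.00288). They called 0 genes between days over both genotypes, 0 sets at day 0, 2 sets at day 7 and 0 sets for the difference of day effects, and the share of peaks at gene ends differed by −0.80 points between genotypes. With the replicate block added, the day effects on X passed at −0.82 in WT, −0.68 in KO and −0.75 over both (adjusted p = 0.0118, 0.0344 and 0.00258), X was higher in KO over both days by 0.42, and the other values were as without the block, including 0.49, 0.14, 0.64, 0.94, 0.79, 0.30 and −3.05, with 0 genes and 0, 2 and 0 sets.

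Peaks ranked by fold gave X coverage of 0.070 for KO minus WT at day 7, −0.92 between days (adjusted p = 0.0402), a skew of 0.061 at day 0, genome1 X coverage of −3.54 in WT and 0 sets for the difference of day effects. With only peaks of a −log10 q of 3 or more, X coverage was 0.25 at day 7 and 0.089 for the difference. The skew was 0.44 at day 0, 0.67 at day 7, 0.55 over both days, −2.93 between days in KO (adjusted p = 0.0675) and 0.23 for the difference. Genome1 X coverage was −3.10 in WT and −2.63 in KO (adjusted p = 0.105), and 0 genes were called between days, with 1 set at day 0, 3 sets at day 7, 5 sets over both days and 0 sets for the difference.

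Numbers of peaks in place of covered length gave X coverage of −0.18 for KO minus WT over both days, a skew of 0.10 at day 0, 0.52 at day 7, 0.31 over both days and 0.42 for the difference, genome1 X coverage of −3.45 in KO (adjusted p = 0.0719) and genome2 X coverage of −0.033 between days. Relative to the median autosome, X coverage was −0.0099 for KO minus WT over both days and −0.97 between days (adjusted p = 0.0425). The replicate block alone gave −0.94 for X between days (adjusted p = 0.0294) and −3.73 for genome1 X in KO (adjusted p = 0.0541).

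Equal numbers of peaks gave X coverage of 0.28 at day 7, −0.75 between days in WT (adjusted p = 0.0103), −0.63 over both genotypes (adjusted p = 0.00262) and 0.23 for the difference. The skew was 0.45 at day 0, 0.35 at day 7 and 0.40 over both days, and genome1 X coverage −2.97 in WT and −2.76 in KO (adjusted p = 0.0939). In this setting 0 genes were called between days, and 1 set at day 0, 1 set at day 7, 1 set over both days and 0 sets for the difference.

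Equal length within each date with the replicate block gave X coverage, KO minus WT, of 0.29 at day 0, 0.55 at day 7 and 0.42 over both days, and day effects of −0.93 in WT, −0.67 in KO and −0.80 over both, differing by 0.26. The skew was 0.53 at day 0, 0.57 at day 7, 0.55 over both days and 0.037 for the difference, and genome1 X coverage −3.06 in WT. It called 0 genes between days and 2 sets at day 7. With chromosomes 6, 8 and 11 also left out, X coverage was 0.46 at day 7, 0.33 over both days, −0.91 in WT, −0.64 in KO, −0.78 over both genotypes and 0.27 for the difference, with genome1 X coverage of −3.06 in WT.

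The log2 of covered kb called 374 genes between days and 1 set between genotypes over both days, and windows at gene ends called 302 genes, 0 sets over both days and 0 sets for the difference. Gene bodies without flanks called 96 genes between days in WT, 1 set at day 7 and 0 sets for the difference, and genes covered in any 1 sample gave 1 set at day 7 and 2 sets for the difference. An estimated correlation left 0 sets in each contrast that had any. By reciprocal overlap of 50%, the shared pooled peaks were 34.2% (KO) and 35.2% (WT) at day 0 and 21.8% (KO) and 27.97% (WT) at day 7, a lower count by construction.

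Leaving out each replicate in turn gave these ranges, with the lone sample of a group assumed to vary like the others. X coverage for KO minus WT ran from −0.60 to 0.50 at day 7 and from −0.23 to 0.32 over both days, and the day effect from −0.93 to −0.76 in WT, from −1.58 to −0.48 in KO and from −1.21 to −0.66 over both, with −0.73 to 0.36 for the difference. KO day 7 replicates 1 and 2 set both ends of the KO ranges. The skew for KO minus WT ran from −0.47 to 0.094 at day 0, from −1.17 to 0.34 at day 7 and from −0.68 to 0.074 over both days, with −0.98 to 0.52 for the difference. Genome1 X coverage ran from −3.69 to −2.97 in WT and from −4.90 to −2.55 in KO, and genome2 X coverage from −0.16 to 0.27. Genes called for KO minus WT ran from 0 to 113 at day 0, from 0 to 357 at day 7 and from 0 to 357 over both days, and between days from 0 to 403 in WT, from 0 to 751 over both genotypes and from 0 to 331 for the difference. The high counts came with a WT group of 1 sample, where many genes at 0 have no spread. Such genes made up most of the calls between genotypes, between days in WT and for the difference. Sets called ran from 0 to 1 at day 7, from 0 to 4 over both days, from 3 to 7 between days in WT, from 3 to 5 in KO, from 3 to 7 over both genotypes and from 0 to 2 for the difference, and the signed adjusted p of the ribosomal set for that difference ran from −0.814 to 0.335. The log2 number of peaks between days ran from −0.72 to 0.50 and covered length from −0.93 to 0.63. For KO minus WT the number of peaks ran from 0.21 to 1.43 and covered length from 0.42 to 1.98. The share of X genes with a peak on 1 allele ran from −4.38 to 1.06 points between genotypes. The share of peaks near gene ends ran from 2.72 to 25.5 points between genotypes and from 0.78 to 23.5 points between days.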

Other observations

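The reading of imprinted genes by allele was chosen only after the result was seen and is given as values.

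At imprinted genes the alleles could be compared only where genome2 peaks were frequent. Impact (chromosome 18, 12954690 to 12992950), a gene expressed from the paternal allele, had a genome2 peak in 8 of 8 samples as deposited and a genome1 peak in 0, while the pooled KO day 7 list had a genome1 peak over 1.06% of it, in a window with a genome2 share of 43.9%. Inpp5f (chromosome 7, 128611181 to 128696436), with a paternally expressed transcript, had a genome2 peak in 8 samples and a genome1 peak in 1. Snrpn had peaks on both alleles in 8 of 8 samples, and Sgce on genome1 in 7 and on genome2 in 8. H19, Igf2r and Dlk1 lie in stretches with little genome2 coverage and had genome1 peaks alone. In the pooled lists, genome1 peaks covered H19 (chromosome 7, 142575530 to 142578146) over 33.5% at day 0 and 100% at day 7 in KO and over 35.5% and 75.2% in WT. They covered Igf2r (chromosome 17, 12682406 to 12769706) over 3.14% and 26.9% in KO and 10.7% and 30.2% in WT, and Dlk1 (chromosome 12, 109452485 to 109463336) over 3.29% and 32.1% in KO and 3.74% and 27.0% in WT. Pooled lists have no replicates, so no test was made, and these genes were named after their values were seen, apart from their place on the fixed list of imprinted genes.

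Some members of fixed lists that did not pass had means that lay apart between the genotypes. Eomes, a regulator of the primitive streak, was covered over 79.3% ± 29.2 in KO day 7 and 22.4% ± 9.42 in WT day 7 (adjusted p = 0.530), and Fst over 39.7% in KO day 7 and 9.60% in WT day 7. The pluripotency gene Dppa4 was covered over 22.8% in KO day 0 and 5.32% in WT day 0. Among imprinted genes, Peg10 and Sgce were listed at 0 in KO and covered over 12.8% and 8.79% in WT day 7, in lists of equal length. In the lists as deposited both were higher in KO at day 7 (effects of 0.024 and 0.14), so the direction rests on the cut. Among repair genes, Trp53bp1 was covered over 1.75% and 3.19% in KO (day 0 and day 7) and 0.109% and 0.841% in WT, higher in KO in 8 of 8 pairs (limma adjusted p = 0.647).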
